A study of Drosophila melanogaster with 36 samples.

How the data were processed

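The tissue was the optic lobe of the fruit fly Drosophila melanogaster, the part of the brain that processes input from the eye, at 9 stages of pupal development from 0 to 96 h after puparium formation. Sorted single cells were captured in droplets and their polyadenylated RNA was sequenced, per the labels' protocols. The 36 libraries are of 2 kinds. The 16 DGRP libraries each pool animals of many strains of the Drosophila Genetic Reference Panel, a collection of inbred wild-derived lines, with all stages together in every library. The 20 w1118 libraries hold a laboratory strain with white eyes, at a single stage per library (4 libraries at 24 h, 8 at 48 h, 4 at 72 h and 4 at 96 h). The set letters A and B in the labels mark separate pools, and the libraries within a set are technical repeats of it per the authors' description of the files. The w1118 libraries labelled 96 h by age carry the word adult in their titles, and were taken as 96 h.

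The authors deposited raw UMI counts (unique molecular identifiers) per gene and cell, with no normalization, in a main table (193727 cells, 24 to 96 h) and an early table (28633 cells, 0 to 24 h). The 2 tables share 13384 cells of 24 h. Cell Ranger 3.1.0 and Seurat 3.1.2 are named in the submitters' processing notes, without their roles. The genome build, the annotation, the use of strand in counting, the filters on cells and the treatment of doublets are not given in the sources used here. No coordinates are therefore printed, antisense and overlapping genes were kept out of the names, and folds of close paralogs, such as the Hsp70 copies, are uncertain because reads can be split between them. Gene symbols and FBgn identifiers were taken from the deposited tables, which pair them for all 17561 genes. A deposited per-cell table gives each cell's strain, which the authors assigned by demultiplexing, and its stage, class, type and subtype. The authors corrected exchanged labels of the T4c and T4d subtypes, per their description of the files. The class letters are not spelled out there. Class N was read as neurons, G as glia and R as photoreceptors, because the summed CPM (counts per gene scaled to the same total in each sum) of the neuron markers was 14620 in N and 867 in G, that of the glia markers 13850 in G and 398 in N, and that of the photoreceptor markers 13030 in R and 529 in N. Class C was not used as a named type, and class x marks 15510 cells of the early table. The shared cells of 24 h held 9429 neurons in the main table and 5249 in the early table. Class x at 24 h therefore holds cells that the main table calls neurons. Early neurons are thus only the labelled part, with another mix of types: T4 and T5 made up 17.9% of them at 24 h, against 10.0% in the main table (means over strain sums). No further filter was applied to cells, no doublet caller was run, and the deposited projection coordinates were not used.

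Cells are not replicates, so UMI counts were summed per strain, set letter and stage, with at least 10 cells per sum. This gave 6 sums at each stage, 3 from set A and 3 from set B. A strain was in both sets at 24 h (line_189), 48 h (line_129), 72 h (line_28) and 96 h (line_748). At these stages n = 6 therefore counts sums and not separate strains, also where types were compared at 48 h. The animals within a strain were pooled, so that p-values measure the spread between strain sums. The cells came from 29 DGRP strains in the main table, 16 in the early table and 31 in either. Depth ranged from 14450039 to 55254218 UMIs per library, from 1137369 to 18745146 UMIs per neuron sum and from 619072 to 6889298 UMIs per early neuron sum. The smallest sums were those of 24 h set B line_189, with 109 neurons in the early table, and 96 h set A line_307, and each sum was left out in turn. All w1118 libraries of a stage and set letter were summed, which gave 5 sums, so the genotype and the kind of library cannot be told apart in that comparison.

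The tests, the gene lists, the rule for named genes and the alternatives were fixed before the data were examined. Counts were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood test, TMM factors, its filter on low counts) with the Benjamini-Hochberg adjusted p below 0.05. The stage contrasts of all neurons came from a fit of the 7 stages of the main table, and the early contrasts from a fit of the 3 stages of the early table. T4 against T5, the T4/T5 subtypes and the lamina types L1 to L5 were tested at 48 h with the strain sum as a block. For w1118 against DGRP, stage was a covariate. For changes shared across types, each of 27 neuronal types with at least 3 strains at 24, 48, 72 and 96 h was tested by itself, and a gene was called shared when it passed in the same direction in at least 90% of the types that tested it. For differences among types, 30 cells were drawn per type, stage and set letter and thinned to equal UMIs (67493 to 73036 UMIs per sum over the draws), for 24 types with 30 cells in both sets at all 7 stages. A gene was called by an F-test and a fitted range of at least 4-fold, in 20 draws. Types were assigned by the authors from expression, so differences between types are partly built into the labels.

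The 23 lists were ecdysone response, synaptic vesicle and active zone, transmitter synthesis and transport, voltage-gated and leak channels, transmitter receptors, the dpr and DIP families, the beat and side families, guidance and adhesion, growth cone cytoskeleton, cytosolic ribosome, oxidative phosphorylation, mitochondrially encoded genes, heat shock, immediate early genes, and markers of neurons, glia, progenitors, dividing cells, photoreceptors, hemocytes, fat body, T4 or T5 neurons, and lamina neurons. Members were counted over all genes tested and again with p-values adjusted over the list alone, and lists were compared with the other genes by camera of limma 3.58.1, with a preset correlation of 0.01 and with an estimated one. Named genes had an adjusted p below 0.05, a mean log2 CPM of at least 5 and, for stage contrasts, no overlap between the strain sums of the 2 stages (for shared changes, in the sums of all neurons). The largest folds were taken: 10 each way for stage contrasts, 8 each way for shared changes and for T4 and T5, 6 each way for early and w1118 contrasts, 4 per lamina type, and 2 to 4 members per list described. Symbols starting with CG, CR, lncRNA, asRNA or tRNA and mitochondrial genes were not named. The edgeR log2 folds and most CPM values use TMM-scaled library sizes. CPM values of single w1118 sums, of summed lists and of w1118 against DGRP cells at a single stage use total UMIs. So do the values of glia per strain at 84 h. Levels on the 2 scales are therefore not strictly comparable.

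The alternatives were DESeq2 1.42.0, its size factors in edgeR, no filter on low counts, each replicate left out, a block on the set letter (or none), types weighted equally, w1118 sets added as samples, other limits on cells, shares and folds, and T4/T5 neurons alone for w1118. Leaving out the 84 h sums was chosen after seeing the data, as was a list of 12 glycolytic enzymes. The set letter pairs samples by design, because all stages of a letter share libraries. Deviations of strain sums from their stage means correlated across genes between stages with a mean r of 0.654 within a letter (lowest 0.311, highest 0.82). In the early table this mean was 0.478. The means between letters, -0.654 and -0.479, mirror these because the stage means were taken over both letters, and are no separate observation. Sums of the same strain in both sets were no more alike (median r 0.9655 over 4 pairs) than sums of other strains (0.971 over 59 pairs).

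Simulated counts with 200 seeded genes were tested for 1 step each of all neurons, early neurons, shared changes and neurons against glia, for types at 48 h, and for w1118, T4 against T5 and L1 to L5. The T4/T5 subtypes were not simulated. Shares recovered are of the seeded genes that were tested. Of 100 genes seeded at 2-fold 84 were tested for T4 against T5, 81 for L1 to L5 and 89 for shared changes. For all neurons 97% of genes changed 2-fold and 100% of those changed 4-fold were recovered among 8437 genes, and 3.9% of the calls were unchanged genes. That share was 5.94% for early neurons, above the 5% aimed at, and at most 4.83% in the other edgeR tests; with DESeq2 it was 9.26% for all neurons and 8.74% for early neurons. Early neurons recovered 90% and 100% of 6926 genes' seeded changes, w1118 against DGRP 99% and 100% (8486 genes), T4 against T5 64.3% and 98.8% (4967 genes), L1 to L5 74.1% and 100% (4412 genes), and neurons against glia 54% and 100% (8585 genes). Shared changes recovered 13.5% at 2-fold and 97.8% at 4-fold (2397 genes), so that small shared changes are largely missed. Among types, 98% of 8-fold and 100% of 16-fold changes were recovered (2217 genes). The 200 seeded genes are far fewer than those called in the data, such as 4075 of 8518 for all neurons from 24 to 48 h. The simulated shares of false calls may therefore not carry over to the data.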

Results

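Messenger RNA was counted in single cells of the optic lobes of pupae to follow how neurons change while they wire up. The main table held 193727 cells at 24, 36, 48, 60, 72, 84 and 96 h after puparium formation, of which 162709 were neurons of 153 types. DGRP strains gave 73613 of these neurons, from 8664 to 14306 per stage. The w1118 flies gave 89096 at 24, 48, 72 and 96 h. The early table added 2212 DGRP cells labelled neurons at 0 h and 3205 at 12 h. There class x made up 64.5% and 52.4% of cells (means over strain sums). Every DGRP stage was represented by 6 strain sums. The median DGRP neuron held 5290 UMIs at 24 h, 5866 at 36 h, 4454 at 84 h and 3566 at 96 h. Neurons made up 70.6% ± 6.59 of DGRP cells at 24 h and 92.8% ± 3.54 at 96 h (SD, n = 6), glia 11.8% and 5.06%, and the unnamed class C 12.8% ± 6.32 and 0.683%. The cells had been sorted by fluorescence, which can set such shares.

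Single genes of the response to ecdysone, the steroid hormone that drives metamorphosis, peaked at different stages in neurons. The list of 19 such genes went both ways at each step (5 rose and 9 fell from 24 to 48 h, 7 and 6 from 48 to 72 h, 4 and 6 from 72 to 96 h; camera, adjusted p = 0.69, 0.99 and 0.56 with an estimated correlation). The nuclear receptor genes Hr3 and Hr4 peaked at 48 h and 36 h: Hr3 stood at 28.4 ± 5.97 CPM at 24 h, 820 ± 54.7 at 48 h and 291 ± 38.4 at 72 h (SD, n = 6 strain sums). Hr4 stood at 375 CPM at 24 h, 4135 ± 569 at 36 h, 3001 ± 292 at 48 h and 99.4 at 96 h. The nuclear receptor gene ftz-f1 was at 123 ± 9.69 CPM at 48 h, 2221 ± 292 at 60 h, 1991 ± 302 at 72 h, 5596 ± 820 at 84 h and 157 ± 28.1 at 96 h. Blimp-1, which encodes a transcriptional repressor, had 1134 CPM at 36 h and 39.5 ± 11.1 at 48 h. Low levels differed between the kinds of library: at 24 h ftz-f1 stood at 44.6 CPM in DGRP neurons and 1.17 in w1118 neurons, and at 72 h Blimp-1 stood at 19.8 and 1.2 CPM. In the w1118 sums Hr3 had 7.64 CPM at 24 h, 807 and 887 at 48 h and 135 at 96 h, and ftz-f1 2161 CPM at 72 h.

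**Figure D1:**
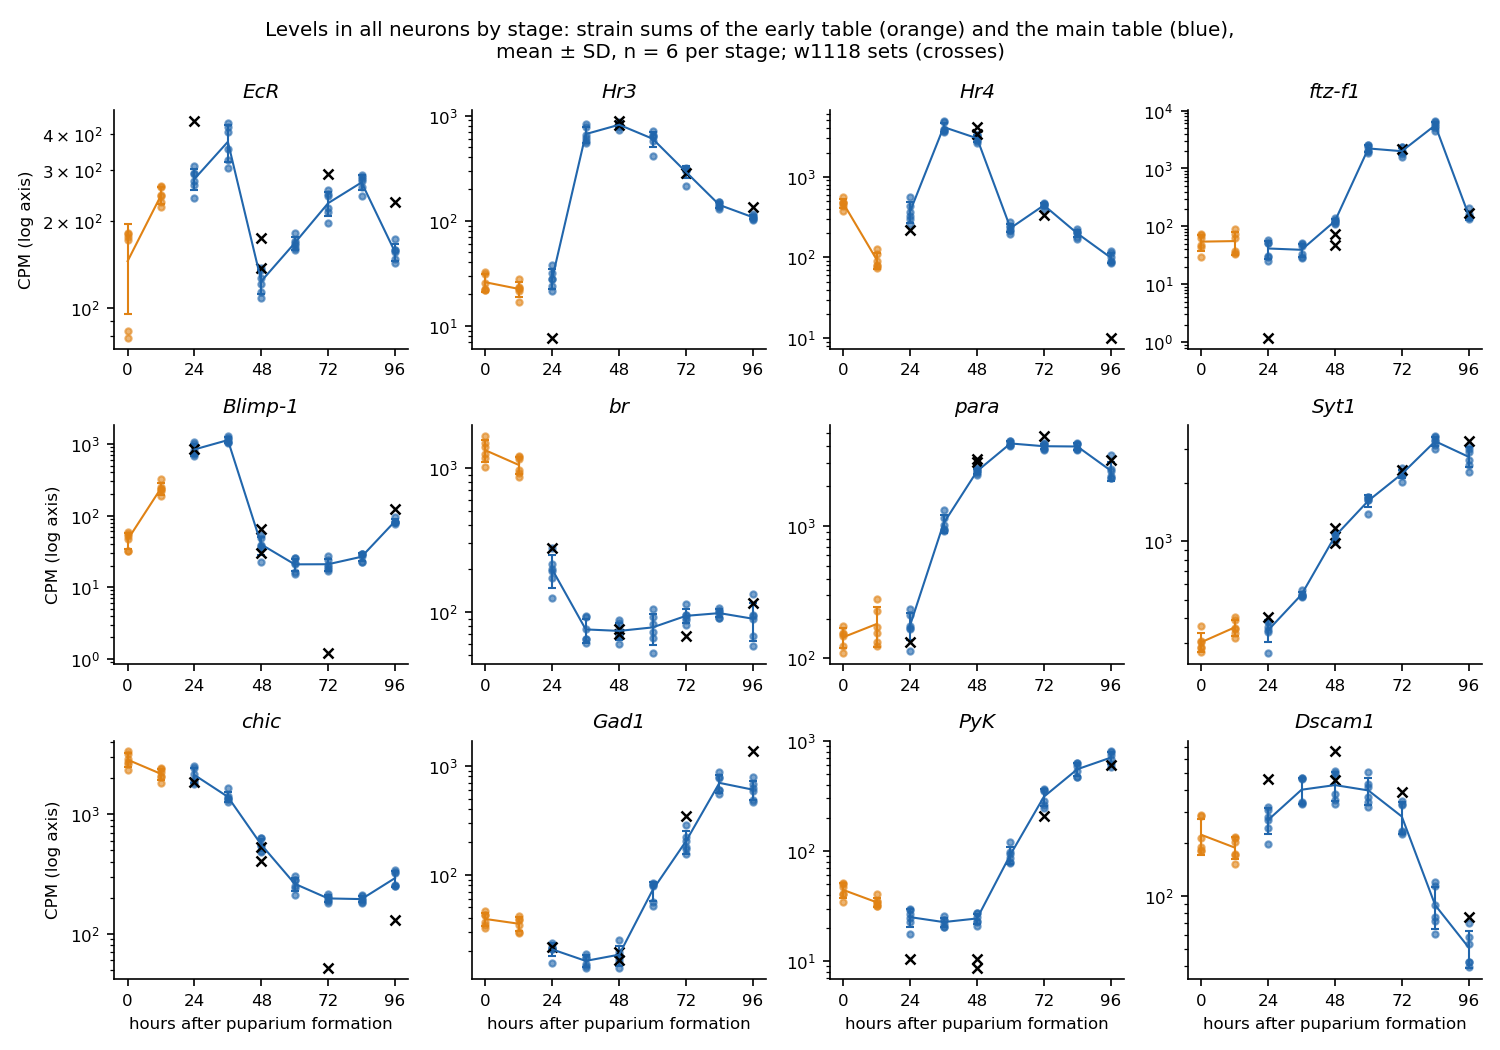
Level of 12 genes in neurons (CPM, log axis) by hours after puparium formation, as points and mean ± SD of 6 DGRP strain sums (blue, main table; orange, early table), with single w1118 sums as crosses. Hr3 and ftz-f1 reach 820 CPM at 48 h and 5596 CPM at 84 h. Levels of DGRP sums are TMM-scaled, while those of w1118 sums use total UMIs.

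Between 24 and 48 h genes for excitability and synapses rose in neurons and genes of the growth cone fell. Hr3 rose by 4.85 on the log2 scale (SE 0.12, adjusted p = 3.6e-30, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Syt12, a synaptotagmin, rose by 5.06 (SE 0.18, from 3.91 ± 1.04 to 128 ± 9.42 CPM). Among genes of a mean log2 CPM of at least 5 the largest rises also included those of Cht6 (4.96), axed (4.93), jp (4.71), inaF-D (4.58), Calx, a sodium and calcium exchanger (4.48), Rbp, an active zone protein (4.04), and twit (3.99). The potassium channel gene slo rose by 4.22 (from 67.5 ± 3.95 to 1241 ± 57.5 CPM). Among the falls at that level Blimp-1 led (-4.39, SE 0.16), followed by hdc (-4.17, from 3614 ± 515 to 199 ± 34.6 CPM). Next came the cell death gene hid (-3.45), Eip71CD (-2.56), Hsp27 (-2.50). The gene of the actin-severing cofilin, tsr, fell by 2.42 (from 2553 ± 284 to 470 ± 33.3 CPM), and the list ended with Sidpn (-2.37), l(1)G0196 (-2.25), l(1)G0193 (-2.21) and Fim (-2.17).

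Of 29 channel genes 24 rose and 1 fell from 24 to 48 h (24 and 1 adjusted over the list alone), among them KCNQ (4.15, at a lower mean level), the sodium channel gene para (3.88, from 179 ± 41.5 to 2595 ± 118 CPM) and NaCP60E (3.83). Of 30 synaptic vesicle and active zone genes 24 rose and 1 fell (25 and 1 adjusted over the list alone), with Syt1 going from 347 ± 44.4 to 1061 CPM. Transmitter receptor genes rose in 31 of 41 and fell in 1 (31 and 2 adjusted over the list alone; ort 3.44, nAChRalpha5 3.13, Rdl 3.05). The dpr and DIP genes, cell surface proteins that bind each other, rose in 23 of 31 and fell in 1 (24 and 2 adjusted over the list alone; dpr5 2.77, dpr18 2.60). Growth cone genes fell in 13 of 29 and rose in 5 (14 and 5 adjusted over the list alone; cib -1.98, chic, which encodes profilin, -1.91). Camera placed these 5 lists apart from other genes with an estimated correlation too (adjusted p from 7.0e-05 for channels to 0.0086 for receptors). Of 67 oxidative phosphorylation genes 65 rose (median 0.58; 65 adjusted over the list alone) and of 84 ribosomal protein genes 78 fell (median -0.37; 79 adjusted over the list alone). Of 21 beat and side genes 18 rose (18 adjusted over the list alone; side-V 1.53, beat-Ib 1.32). For these 3 lists camera's test was lost, with adjusted p = 0.20, 0.15 and 0.44 with an estimated correlation.

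Other lists were mixed from 24 to 48 h. Of 19 ecdysone response genes 5 rose and 9 fell. Of 69 guidance and adhesion genes 27 rose and 14 fell (CadN2 2.24, Con 1.95, Lac -2.06), and of 13 transmitter synthesis genes 4 rose and 2 fell (Tbh 2.46, DAT 1.42). These 3 lists had the same counts adjusted over the list alone. Heat shock genes rose in 2 of 15 and fell in 4 (2 and 3 adjusted over the list alone; stv 2.29), mitochondrially encoded genes rose in 4 of 15 (3 adjusted over the list alone), and immediate early genes rose in 3 of 6 and fell in 2 (3 and 2 adjusted over the list alone; Atf3 2.54). Of 8 neuronal markers 5 rose and 1 fell (median 1.09; camera, adjusted p = 0.0029 with an estimated correlation), and 3 of 12 glial markers rose (nrv2 0.92, Eaat1 0.72). Falls were counted for 2 of 10 cell cycle and 2 of 8 progenitor markers and 4 of 8 T4 or T5 markers. Of 14 photoreceptor markers 1 rose, as did 1 of 10 lamina markers. Beside these groups, the summed level in neurons was 264 ± 18.3 CPM at 24 h and 365 at 48 h for glial markers, 2417 ± 690 and 1627 for progenitor markers and 8115 and 13980 for neuronal markers. It was 57.0 and 264 CPM for hemocyte markers and 31.9 and 111 for fat body markers. In all, 2147 genes rose and 1928 fell, 4075 of 8518 tested. Which direction held more genes depended on the scaling: with DESeq2's size factors 1939 rose and 2221 fell.

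From 48 to 72 h transmitter and synaptic genes rose, glycolytic enzymes were among the largest rises, and growth cone genes fell further. Among genes of a mean log2 CPM of at least 5 the largest rises were those of Proc (4.52), zld (4.09), ftz-f1 (4.06, SE 0.18, adjusted p = 1.1e-21, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), Adk1 (3.87), and Gbs-76A (3.77). Next came PyK, the pyruvate kinase gene (3.72, from 24.4 ± 2.63 to 311 ± 53.6 CPM), Rab27 (3.56), Pfk (3.48) and Scp2 (3.47). Gad1, whose enzyme makes the transmitter GABA, rose by 3.51 (from 18.4 ± 3.84 to 203 ± 47.0 CPM). At that level the largest falls were those of Cht6 (-3.23), Myo81F (-3.23), Hsp67Bc (-3.06), Btk29A (-3.05), the adhesion gene Nrt (from 710 to 85.9 CPM), Hr4 (-2.71, from 3001 ± 292 to 443 ± 26.8 CPM), Hsp67Ba (-2.37), plum (-2.22), Nrk (-2.22) and HINT1 (-2.18). Of 30 synaptic genes 27 rose and 1 fell, and of 13 transmitter synthesis genes 9 rose and 1 fell (9 and 2 adjusted over the list alone; ChAT, for acetylcholine, 2.67, Ddc 2.60). Of 29 growth cone genes 21 fell and 1 rose (median -0.96; fax -2.02, betaTub56D -1.81, pod1 -1.76, Act42A -1.66). The counts for synaptic and growth cone genes were equal adjusted over the list alone, and all 3 lists differed from other genes with an estimated correlation (camera, adjusted p = 7.3e-05, 0.00012 and 4.4e-05).

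Other lists moved from 48 to 72 h without passing camera's test under an estimated correlation. Channel genes rose in 20 of 29 and fell in 2 (Elk 3.4, Slob 2.45; adjusted p = 0.12 with an estimated correlation) and receptor genes rose in 26 of 41 and fell in 2 (Grik 2.28, Nmdar2 2.17; adjusted p = 0.26 with an estimated correlation). Guidance and adhesion genes fell in 33 of 69 and rose in 10 (otk -2.10, hbs -2.03, rst -2.02; adjusted p = 0.74 with an estimated correlation). Oxidative phosphorylation genes rose in 63 of 67 (median 0.66; adjusted p = 0.22 with an estimated correlation) and ribosomal protein genes fell in 61 of 84 (median -0.32; adjusted p = 0.32 with an estimated correlation). Adjusted over the list alone the counts were 20 and 2, 27 and 2, 33 and 10, 65, and 64. Members of the dpr and DIP list rose in 13 of 31 and fell in 2 (DIP-theta 1.80), and of the beat and side list in 10 and 1 of 21 (beat-VII 2.16). Mitochondrially encoded genes rose in 8 of 15, and heat shock genes rose in 8 of 15 and fell in 5 (Hsp70Ba 2.97, Hsp68 2.72). Of 10 lamina markers 7 fell, and of 12 glial markers 3 rose (Eaat1 1.91), with summed glial markers at 371 CPM at 72 h. Of 6 immediate early genes 2 rose, Hr38 among them. In all 2145 genes rose and 2339 fell, 4484 of 8518. With every type given equal weight 1032 rose and 2906 fell.

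**Figure D2:**
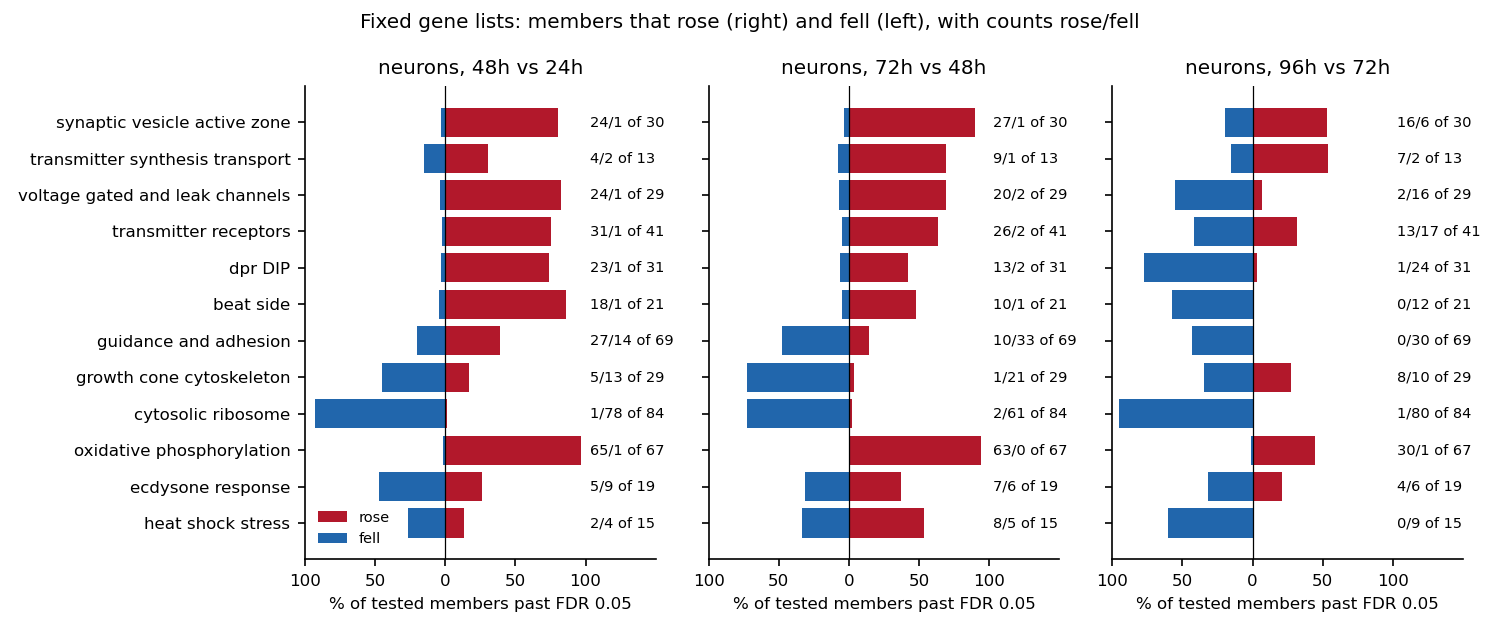
Percent of the tested members of 12 gene lists that rose (right) or fell (left) in DGRP neurons at each of 3 steps of 24 h, with counts printed beside the bars (edgeR, n = 6 strain sums per stage). Ribosomal protein genes fell at each step, and channel genes rose in 24 of 29 in the first step and fell in 16 of 29 in the last.

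From 72 to 96 h ribosomal protein genes fell together and many genes of recognition and excitability decreased. Of 84 ribosomal protein genes 80 fell and 1 rose (median -0.89; 80 and 2 adjusted over the list alone), and camera's test held with an estimated correlation (adjusted p = 5.2e-05). All 92 genes of the list, tested or not, took 222100 CPM at 24 h, 162000 at 48 h, 116600 at 72 h and 71580 at 96 h. RpS15 went from 4060 to 1008 CPM over the series. The median neuron had 5378 UMIs at 72 h and 3566 at 96 h. The dpr and DIP genes fell in 24 of 31 and rose in 1 (25 and 1 adjusted over the list alone; dpr14 -1.24, DIP-theta -1.11; adjusted p = 0.076 with an estimated correlation). Falls were counted for 12 of 21 beat and side genes (12 adjusted over the list alone; beat-Vc -1.22, side-VIII -1.16; adjusted p = 0.25 with an estimated correlation) and 30 of 69 guidance genes (34 adjusted over the list alone; Sema2a -1.63, Wnt4 -1.44; adjusted p = 0.56 with an estimated correlation). Channel genes fell in 16 of 29 and rose in 2 (21 and 3 adjusted over the list alone; slo -1.52, cac -1.43; adjusted p = 0.19 with an estimated correlation). Heat shock genes fell in 9 of 15 (9 adjusted over the list alone; Hsp83 -1.38; adjusted p = 0.42 with an estimated correlation). Synaptic genes still rose in 16 of 30 and fell in 6 (16 and 6 adjusted over the list alone; Fife 1.33; adjusted p = 0.42 with an estimated correlation), and transmitter synthesis genes rose in 7 of 13 and fell in 2 (7 and 2 adjusted over the list alone; adjusted p = 0.076 with an estimated correlation).

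Among genes of a mean log2 CPM of at least 5 the largest rises from 72 to 96 h were those of Sytalpha (3.80), Ddc (2.87), Cbp53E, a calcium-binding protein (2.85, from 375 ± 61.5 to 2687 ± 397 CPM) and Nhe2 (2.48). They were followed by Eip71CD (2.45), l(1)G0196 (2.41), Drep3 (2.28), Gpdh1, a glycolytic side enzyme (2.26), Blimp-1 (1.99) and Fas1 (1.96). At lower mean levels Kr-h1 (5.52) and sr (5.10) rose more, named after their values were seen. At the level above, the largest falls were those of inaF-D (-5.64), SIFaR (-3.70), ftz-f1 (-3.65), sty (-3.20), Oatp74D (-2.87), SP1029 (-2.83), OtopLa (-2.42), Syt12 (-2.29) and pnut (-2.28). Dscam1, a cell recognition gene, fell by 2.48 (from 282 to 51.3 CPM). Receptor genes went both ways, with 13 rising and 17 falling of 41 (ort 1.77, nAChRalpha5 -1.92), as did growth cone genes with 8 and 10 of 29 (ena -1.62) and ecdysone response genes with 4 and 6 of 19. Immediate early genes rose in 3 of 6 and fell in 1, with sr among the rises. Oxidative phosphorylation genes rose in 30 of 67 and fell in 1 (adjusted p = 0.56 with an estimated correlation). Of 12 glial markers 6 rose and 1 fell (Tret1-1 1.97, Eaat1 1.5), and the summed glial markers stood at 648 ± 84.3 CPM at 96 h. Summed photoreceptor markers were at 525 CPM at 72 h and 962 at 96 h. In all 1556 genes rose and 1736 fell, 3292 of 8518 by edgeR; with types weighted equally 983 rose and 973 fell.

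In the first day single genes of the hormone response and of surface recognition changed in the cells labelled neurons. Most members of the ecdysone response list and of the guidance and adhesion list did not pass. Of the dpr and DIP genes more passed than not from 12 to 24 h, but not from 0 to 12 h. The labelled cells themselves shifted: T4 and T5 made up 15.8% of early neurons at 0 h, 25.4% at 12 h and 17.9% at 24 h. Class x went from 64.5% of cells at 0 h to 48.4% at 24 h (means over strain sums). No fit within types was made for these steps, so changes within cells and a shift in the labelled cells cannot be told apart. From 0 to 12 h Kr-h1, a target of juvenile hormone, fell by 6.62 on the log2 scale (SE 0.33), from 214 ± 80.2 to 2.11 ± 0.979 CPM (SD, n = 6), and the RNA-binding protein gene Imp fell by 3.47. The genes vri (-4.76), Sox14 (-4.13), FER (-2.97) and zld (-2.45) fell too. Strain sums of 0 h differed widely, from 84.4 to 595 CPM for Imp and from 42.8 to 503.5 CPM for Sox14, and vri stood at 121 ± 81.6 CPM. The sizes of these falls are therefore uncertain, although sums of 0 h and 12 h did not overlap. At 48 h Kr-h1 stood at 1.82 CPM in DGRP neurons and 0.0215 in w1118 neurons. At a mean log2 CPM of at least 5 rises were led by Blimp-1 (2.37, from 46.0 to 242 CPM), Oatp74D (2.03), Scgalpha (1.57), fred (1.52), jeb (1.49) and Nlg2 (1.38). From 12 to 24 h Eip74EF (2.86), Hr4 (2.20), Blimp-1 (2.02), the gap junction gene shakB (1.98, from 286 to 1130 CPM), OtopLc (1.89) and sNPF (1.87) rose. The hormone-induced transcription factor gene br fell by 2.19 (from 1051 ± 146 to 229 CPM), with nerfin-1 (-2.22), zld (-1.76), JMJD4 (-1.48), eEF1alpha1 (-1.20) and Pal2 (-0.98).

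Guidance and adhesion genes rose in 17 of 69 and fell in 2 from 0 to 12 h, and rose in 21 from 12 to 24 h (28 and 3, then 26 and 1, adjusted over the list alone; adjusted p = 0.79 and 0.40 with an estimated correlation). The dpr and DIP genes rose in 7 and then 13 of 31, with 3 falling in the latter step (13 and 3, then 14 and 3, adjusted over the list alone; adjusted p = 0.37 and 0.21 with an estimated correlation). Receptor genes rose in 14 of 38 from 12 to 24 h and fell in 1 (17 and 2 adjusted over the list alone; adjusted p = 0.21 with an estimated correlation), and ecdysone response genes rose in 5 of 18 and fell in 1 (7 and 1 adjusted over the list alone; adjusted p = 0.21 with an estimated correlation). From 0 to 12 h 4 ecdysone response genes rose and 4 fell (4 and 4 adjusted over the list alone; adjusted p = 0.98 with an estimated correlation). By edgeR 255 genes rose and 346 fell from 0 to 12 h (601 of 6932), and 428 rose and 224 fell from 12 to 24 h (652). With the set letter as a block, which pairs sums that shared libraries, the counts were 1326 (675 rose, 651 fell) and 1516 (899 rose, 617 fell). The direction with more genes thus turned for the step from 0 to 12 h.

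Some changes were common to neuronal types. Each of 27 types was tested by itself. From 24 to 48 h 178 genes (113 up, 65 down) passed in at least 90% of the types testing them, among 2529 genes tested in enough types. From 48 to 72 h 275 passed (152 up, 123 down), and from 72 to 96 h 98 (44 up, 54 down). Hr3 rose in 27 of 27 types (median log2 fold 5.33, from 3.57 to 7.09), as did para (4.17) and Rbp (4.01). The other large common rises were jp (5.05), Syt12 (4.99, 22 of 22 types), axed (4.36), Calx (4.28) and Rgk1 (4.07). Common falls from 24 to 48 h were hdc (-4.87), Blimp-1 (-4.85), hid (-4.22), Sidpn (-2.88), l(1)G0193 (-2.88), tsr (-2.44), Hsp27 (-2.38) and Lac (-2.31). From 48 to 72 h ftz-f1 rose in 27 of 27 types (3.99), with Gbs-76A (3.97), Kank (3.87), 5-HT2A (3.83), Ca-alpha1T (3.61), and the glycolytic genes PyK (3.46) and Pglym78 (3.44), and Nmdar2 (3.42). The falls were Hsp67Bc (-4.76), Myo81F (-4.17), Nrt (-3.11), Hr4 (-2.94), Btk29A (-2.77), Df31 (-2.28), Hsp67Ba (-2.25) and E2f1 (-2.20). From 72 to 96 h Kr-h1 rose in 18 of 18 types (5.44), with Cbp53E (4.48), Gpdh1 (2.51), l(1)G0196 (2.35), Fas1 (2.28), Blimp-1 (2.25), Fim (2.0) and Mkp3 (1.99). The falls were ftz-f1 (-4.19), SIFaR (-3.96), SP1029 (-3.01), Oatp74D (-2.71), Syt12 (-2.39), OtopLa (-2.36), Dscam1 (-2.22) and Hr4 (-1.90).

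By list, 12 of 24 channel genes and 8 of 27 synaptic genes rose in common from 24 to 48 h, while 4 of 23 growth cone genes fell (chic, cib, pod1, tsr). From 48 to 72 h 12 synaptic genes rose, 9 growth cone genes fell, and both transmitter synthesis genes that could be scored, ChAT and VAChT, rose. Of 81 ribosomal protein genes 2, 11 and 21 fell in common in the 3 steps. The dpr and DIP genes held 2 common rises of 16 in the first step (dpr14, dpr18). Types share animals and are not independent. With 75% of types required the counts were 393, 574 and 204, and with sums of at least 20 cells, which leaves 12 types, 362 and 167 for the first and last step. Without the filter on low counts 154 genes were shared from 48 to 72 h.

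More genes differed among neuronal types at later stages, up to 60 h. With equal cells and UMIs, 642 genes differed by at least 4-fold among 24 types at 24 h, 825 at 36 h, 949 at 48 h, 1136 at 60 h, 1124 at 72 h, 1115 at 84 h and 1141 at 96 h (edgeR's F-test). Means over 20 draws were 647.5 ± 12.9 at 24 h and 1105.3 ± 24.8 at 96 h (SD over draws), and the ranges from 60 h on overlapped. As a share of the genes tested, which changed in number, they made up 27.9% at 24 h, 34.8% at 36 h, 40.3% at 48 h, 49.3% at 60 h and 49.9% at 72 h. The share was highest at 84 h (53.4%, from 51.3 to 55.1% over draws) and lower again at 96 h (47.6%). Of the genes called, 373 genes differed at all 7 stages and 517 at a single stage. The surface protein families differed among types at nearly every stage: on average 18.8 of 21.2 tested dpr and DIP genes at 24 h and 25.75 of 28 at 96 h, and 18.3 of 18.85 and 20 of 20.05 beat and side genes. Channel genes differed in 11.75 of 15.05 at 24 h and 19.5 of 24.45 at 96 h, and transmitter synthesis genes in 5.80 of 5.80 and 10.5. Of about 64 oxidative phosphorylation genes 1.25 differed at 24 h, 22.65 at 48 h, 46.5 at 72 h and 29.4 at 96 h, and of 81 ribosomal protein genes 2 at 96 h. With all cells and no thinning, the counts were 1092, 1469, 1630, 1891, 1834, 1824 and 1667 from 24 to 96 h, so there the count was lower at 96 h than at 60 h. The authors assigned types from expression, so some of these differences are part of the type labels.

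**Figure D3:**
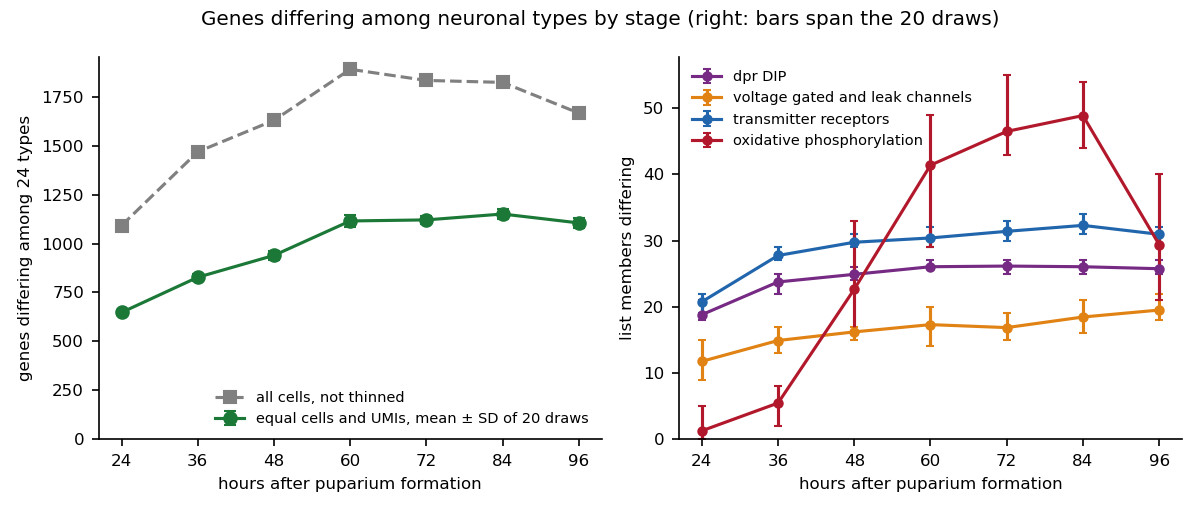
Left, number of genes that differ at least 4-fold among 24 neuronal types (y axis) by hours after puparium formation, as mean ± SD of 20 draws of equal cells and UMIs, with all cells unthinned beside it. Right, number of differing members of 4 gene lists, with bars spanning the draws; oxidative phosphorylation genes go from 1.25 at 24 h to 46.5 at 72 h.

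T4 and T5, sister types that detect motion of bright and of dark edges, differed at 48 h in 276 genes of 4973 (117 higher in T4, 159 higher in T5; edgeR's quasi-likelihood test with the strain sum as a block, n = 6, 20 to 184 cells per sum). The transcription factor gene TfAP-2 was higher in T4 by 4.38 on the log2 scale (279 ± 21.9 CPM against 13.3 ± 8.38 in T5), with dpr3 (3.64), dpr2 (3.48), the neuropeptide gene AstA (3.34), side (2.86), spab (2.72), beat-VI (2.26) and CCKLR-17D3 (2.04). DIP-theta was lower in T4 (-4.76, 5.72 CPM against 169 in T5), with E(spl)m6-BFM (-3.17), the serotonin receptor gene 5-HT1A (-1.95), eys (-1.56), E(spl)malpha-BFM (-1.46), side-VIII (-1.43), Stacl (-1.25) and Pkc53E (-1.11). Of 26 channel genes 7 were higher in T4 and 1 in T5 (11 and 1 adjusted over the list alone; Slob 1.56, KCNQ 1.30), which held with an estimated correlation (camera, adjusted p = 0.043). Of 65 guidance and adhesion genes 16 were higher in T5 and 2 in T4 (18 and 2 adjusted over the list alone; adjusted p = 0.24 with an estimated correlation). The dpr and DIP list had 4 genes each way of 19, with the same counts adjusted over the list alone. Of 8 T4 or T5 markers 1 was higher in each. Without the block 79 genes passed (45 higher in T4, 34 in T5), and DESeq2 called 167 (77 and 90).

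Among the T4 and T5 subtypes, a and b (which respond to horizontal motion) were set against c and d (vertical motion) at 48 h. Of 4856 genes 450 differed, 220 higher in a and b and 230 in c and d (edgeR, n = 6, 13 to 186 cells per sum). The transcription factor gene dac was higher in a and b by 6.07 (313 ± 112 CPM against 4.14 ± 4.19), with Eip63F-1 (5.47), sano (5.39), beat-IIIb (5.01), DIP-theta (4.65), AstC-R1 (4.47), Dscam3 (4.47) and the adhesion gene Fas2 (4.24). Lower in a and b were Con (-5.03), klg (49.4 CPM against 1439), 5-HT1A (-4.37), the Slit receptor gene robo2 (-4.21), the transcription factor genes pros (-4.20) and bi (-3.94), side-II (-3.88) and AstA (-3.84). The dpr and DIP genes split into 5 higher in a and b and 6 in c and d of 20, beat and side genes into 3 and 5 of 14, and guidance genes into 17 and 14 of 64 (6 and 9, 4 and 6, and 21 and 14 adjusted over the list alone). Camera set none of these 3 lists apart with an estimated correlation (adjusted p = 0.89, 0.37 and 0.84 with an estimated correlation). Without the block 231 genes passed.

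**Figure D4:**
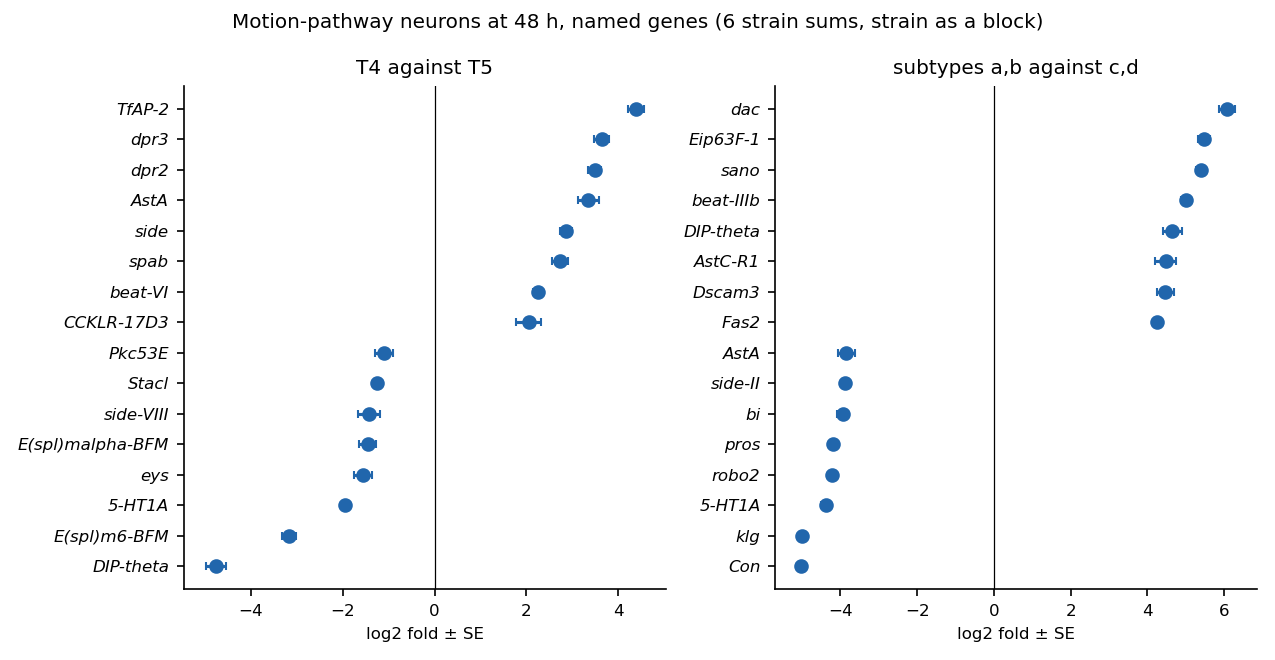
Log2 fold ± SE of the named genes at 48 h for T4 against T5 (left) and for subtypes a and b against c and d (right), from 6 strain sums each. TfAP-2 lies at 4.38 and DIP-theta at -4.76 on the left, and dac at 6.07 and Con at -5.03 on the right.

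The lamina neuron types L1 to L5, which take up the signals of the photoreceptors, differed at 48 h in 2927 of 4487 genes (edgeR's F-test, strain sum as a block, n = 6, 28 to 67 cells per sum). Against the mean of the other types, 990 genes were higher and 782 lower in L1, 1130 and 982 in L2, 666 and 646 in L3, 949 and 1095 in L4, and 734 and 488 in L5. L1 was set apart by svp (455 ± 75.5 CPM against 4.21; log2 fold 6.74), Pka-C3 (6.39), hig (6.33) and s-cup (5.98). L2 stood apart by bab1 (480 CPM against 1.09; 8.67), Apoltp (6.07), sli (5.94) and bab2 (5.92). L3 expressed the guidance genes NetA (569 CPM against 0.873; 9.14) and NetB (8.26), erm (8.58) and dpr16 (8.33). L4 expressed DIP-beta (812 CPM against 4.72; 7.29), KCNQ (7.25), bsh (6.84) and Had1 (6.29), although bsh was high in L5 too (418 CPM, against 799 in L4). L5 expressed the neuropeptide gene Ptth (977 ± 314 CPM against 0.267; 10.84), pdm3 (8.47), the potassium channel gene eag (7.02) and GluRIA (6.46). All 22 tested dpr and DIP genes, 12 of 13 beat and side genes, 25 of 26 channel genes (26 adjusted over the list alone), 31 of 32 receptor genes and 64 of 66 guidance genes differed. So did 82 of 83 ribosomal protein genes and 63 of 64 oxidative phosphorylation genes.

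Neurons of w1118 and DGRP flies were compared over 24, 48, 72 and 96 h with stage as a covariate (5 w1118 sums, 24 DGRP sums). In w1118 1942 genes were higher and 1418 lower, 3360 of 8678 (edgeR). Mitochondrially encoded genes were higher in 14 of 15 (median 1.26; 14 adjusted over the list alone), and this held with an estimated correlation (camera, adjusted p = 0.0057). Without each w1118 sum in turn 13 to 15 were higher (median from 1.12 to 1.35). Their share of all UMIs in the w1118 sums was 2.73% at 24 h, 2.88% and 4.67% at 48 h (sets A and B), 3.43% at 72 h and 4.49% at 96 h. The DGRP sums ranged from 2.28 to 2.84% at 24 h, 2.38 to 3.05% at 48 h, 2.52 to 3.22% at 72 h and 3.02 to 4.09% at 96 h, so the w1118 sums of 24 h and of 48 h set A lay inside the DGRP range. The named genes higher in w1118 were Cp110 (1.58), snRNA:7SK (1.33), 18SrRNA-Psi:CR41602 (1.33), Nca (1.28), AcCoAS (1.25) and TyrR (1.14). ImpL1 was lower in w1118 by 6.46 on the log2 scale, at 0.576 ± 0.529 CPM against 54.2 ± 12.8 in DGRP neurons. DGRP glia held the same gene at 45.3 CPM at 24 h. ImpE2 (-3.15), Cht5 (-2.33), Cpr62Bc (-2.28), Tsf1 (-2.10) and E(spl)mbeta-HLH (-2.07) were lower in w1118 too. Single stages differed: at 24 h ImpE2 stood at 125 CPM in w1118 and 83.8 in DGRP neurons, and Cht5 at 75.9 and 40.9.

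Markers of other cells moved with these groups: 7 of 10 cell cycle markers (CycB -3.47, aurB -3.42; adjusted p = 0.24 with an estimated correlation), 5 of 8 progenitor markers (E(spl)mgamma-HLH -5.20; adjusted p = 0.089 with an estimated correlation) and 4 of 12 glial markers (wrapper -2.70; adjusted p = 0.38 with an estimated correlation) were lower in w1118 neurons. Synaptic genes were higher in w1118 in 19 of 30 and lower in 1, channel genes in 17 and 2 of 29, receptor genes in 23 and 2 of 41, and guidance genes in 36 and 1 of 69 (19 and 1, 17 and 3, 23 and 2, and 37 and 1 adjusted over the list alone; adjusted p = 0.38, 0.56, 0.38 and 0.56 with an estimated correlation). Ribosomal protein genes were lower in 32 of 84 and higher in 3 (35 and 3 adjusted over the list alone; adjusted p = 0.56 with an estimated correlation). Genotype and kind of library differ together here and cannot be told apart. In T4 and T5 neurons alone 1652 genes differed.

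**Figure D5:**
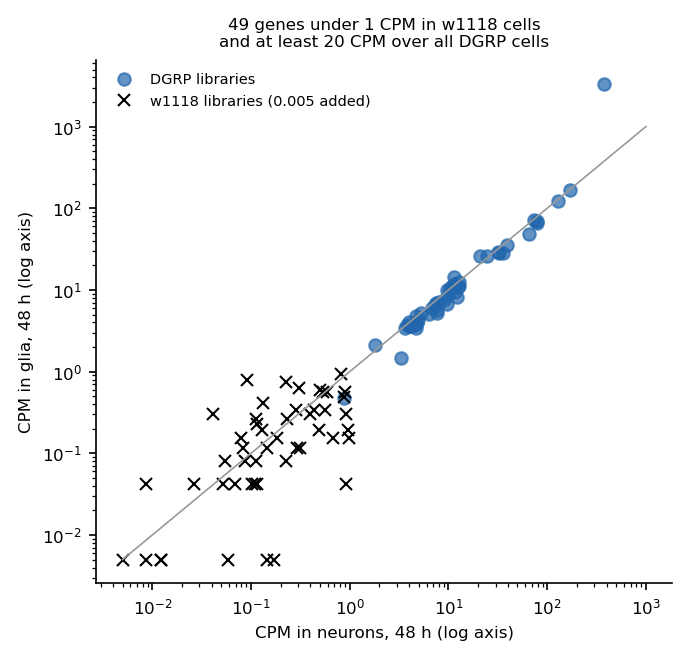
Level in glia (y axis) against neurons (x axis) at 48 h, in CPM on log axes, of 49 genes that w1118 neurons and glia nearly lack; each gene is drawn for DGRP (blue) and for w1118 cells (crosses, 0.005 added), with a line of equal levels. In DGRP cells most genes lie near that line (Spearman's rho 0.983 across genes).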

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

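The tests of a changed makeup of neuronal types, in all neurons and for ribosomal protein genes, were chosen after the results were seen. The others were written before, except the comparison of UMI gaps for ribosomal protein genes. Among gene levels 7 of 126 groups of 6 strain sums held a sum far from the other 5, and among cell shares and depths 10 of 90; chance gives about 1 in 20.

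Genes lower in w1118 than in DGRP neurons form the first pattern. Genes that w1118 neurons and glia nearly lack correlated between DGRP neurons and DGRP glia with a rho of 0.983 across 49 genes at 48 h, and their median log2 ratio of neurons to glia was 0.161 (quartiles 0.041 and 0.266). At 24, 72 and 96 h the median was 0.333, 0.332 and 0.325 (highest upper quartile 0.514) and rho 0.97, 0.97 and 0.96, so that levels in neurons were close to those in glia at each stage, which argues against expression by the DGRP neurons alone. For such genes free RNA shared by all cells of the pooled DGRP libraries is a candidate source, and it may hold up low off-stage levels of stage-bound genes and so understate DGRP folds. Genotype differs along with the kind of library, so for genes expressed in both kinds genotype and library cannot be told apart, and how much of the 1418 lower genes free RNA accounts for stays open.

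Ribosomal protein genes were lower at 96 h than at 72 h. Within 72 h neurons the log2 ratio of ribosomal shares between cells of fewer and of more UMIs was -0.176 (SD 0.029, n = 6 strain sums). By the limits written before, which asked for -0.352 or lower if fewer UMIs per neuron were the cause, this value was undecided. It spanned a gap of -1.081 log2 UMIs, while the stages differed by -0.704 over a gap of -0.475, and at 96 h the ratio was 0.163. This comparison of gaps, which was outside those limits, goes against fewer UMIs per neuron as the whole cause but does not decide it. In w1118 neurons of set A ribosomal protein genes took 9.72% of UMIs at 72 h and 4.49% at 96 h. The median w1118 neuron had 5081 and 3802 UMIs at these stages. A changed makeup of types is excluded as the whole cause, since the median change within 27 types was -0.589 (from -1.08 to -0.2). Cells of few and of many UMIs within a stage can differ in type and, in the pooled DGRP libraries, in their share of free RNA. A lower ribosome supply at the end of pupal life stays open and untested.

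Many genes changed between stages in all neurons, whose mix of types can shift. Over 1694 genes called from 24 to 48 h, the median fold within types followed the fold of all neurons with a slope of 1.031 (SE 0.008), with 98% in the same direction, and the later steps gave 0.986 and 0.992. A changed makeup of neuronal types is therefore excluded as the main cause for these genes, which are the ones tested in enough types. It stays open for the other 2381 genes called from 24 to 48 h: their folds with types weighted equally followed those of all neurons with a slope of 0.588 (SE 0.01), with 97.4% in the same direction. With types weighted equally 1032 genes rose from 48 to 72 h in place of 2145, and 1956 changed from 72 to 96 h in place of 3292.

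Other splits of the same sums into groups of the same sizes were drawn at random, with the real one included. Each of these random splits gave fewer genes by edgeR than the real one. This argues against chance for the counts of all neurons and of w1118. For the early steps splits that follow the shared libraries gave more. For T4 and T5, the subtypes and L1 to L5 the splits decide nothing, because the labels were assigned from the same expression. For shared changes 21 splits are too few to exclude chance. From 24 to 48 h 1 of 40 splits, the real one, gave as many as 4075 genes (highest other 2482); from 48 to 72 h 1 of 40 gave 4484 (2934) and from 72 to 96 h 1 of 40 gave 3292 (1689). Among the 21 splits that kept the set letters balanced, as the real one does, the highest others were 2195, 2817 and 1689; the splits by set letter gave 2007, 1813 and 2631. For the early steps the highest others were 217 against 601 and 0 against 652 (1 of 40 each), but the splits by set letter gave 1646 and 1841, which points to a structure of the samples; with the letter as a block 1326 and 1516 genes passed. For w1118 the values were 3360 and 2 (1 of 40), for T4 and T5 276 and 146 (1 of 32), for the subtypes 450 and 190 (1 of 32), for L1 to L5 2927 and 530 (1 of 40), and for shared changes 178, 275 and 98 against 0 each (1 of 21).

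Single strain sums stood far from the other 5 of their stage as follows. Hr3 was at 214 CPM at 72 h (others 294 to 316), Blimp-1 at 94.4 CPM at 96 h (77.1 to 82.6), Kr-h1 at 5.29 CPM at 72 h (1.5 to 2.79), para at 3450 CPM at 96 h (2290 to 2710), Syt1 at 563 CPM at 36 h (518 to 532) and at 1390 CPM at 60 h (1630 to 1690), and Gad1 at 15.3 CPM at 24 h (20.9 to 23.6). Class C made up 15.9% of cells at 36 h in a strain (others 6.21 to 9.59%), neurons 96.2% at 84 h (92.4 to 93.5%), photoreceptors 1.15% at 84 h (0 to 0.2%) and glia 11.9% at 96 h (2.16 to 5.63%). T4 and T5 made up 3.83% of neurons in a strain at 72 h (11.5 to 15.7%) and 3.67% in an early strain at 24 h (18.3 to 25.3%), which was the thin sum of set B line_189. In the early table glia made up 6.52% at 12 h in set B line_437 (0.498 to 1.80%), which also had 1670 cells (1150 to 1340), and the median UMIs per cell were 4040 at 0 h (3500 to 3670) and 4450 at 12 h (4020 to 4160) in a strain each. The low Hr3 sum was set B line_382, and the high Blimp-1, para and glia values at 96 h were all from set A line_307.

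Changes that differed between neurons and glia, by an interaction in edgeR, numbered 2534 genes from 24 to 48 h, 2921 from 48 to 72 h and 2263 from 72 to 96 h, of 8847. Makeup was not tested in glia, so a shift in their types may contribute to these numbers. Among ecdysone response genes the difference of log2 changes, neurons minus glia, was -4.393 for Blimp-1 and 2.297 for Hr3 from 24 to 48 h, -1.777 for Eip74EF and -1.291 for Eip78C from 48 to 72 h, and -2.048 for Hr4 and 1.887 for ImpE1 from 72 to 96 h. Blimp-1 in glia was at 16.2 and 16.1 CPM at 24 and 48 h, while at 72 h DGRP neurons had 19.8 CPM and w1118 neurons 1.2.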

How the results depend on the processing

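Depth limits small changes in thin sums. Of the simulated 2-fold changes that were tested, 64.3% were recovered between T4 and T5 and 13.5% when a gene had to pass in most types. Of 4664 values of named genes under the other settings 4632 kept their direction and side of the threshold, 32 kept only the direction and 0 reversed. Leaving out the 84 h sums, chosen after seeing the data, kept all 60 of its named values and gave 4159, 4499 and 3281 genes for the 3 steps from 24 to 96 h. The direction with more genes turned under some settings. From 24 to 48 h 2147 rose and 1928 fell, against 1939 and 2221 with DESeq2's size factors, and without the 84 h sums 1977 rose, which is 47.5% of the genes that changed. From 48 to 72 h 2145 and 2339 became 2310 and 2189 without the 84 h sums. From 72 to 96 h 1556 and 1736 became 1644 and 1637 without them, and 983 and 973 with types weighted equally. Where a count moved by over 1.5 times, the cause was not tested unless given.

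With the set letter as a replicate block the early counts were 1326 and 1516 in place of 601 and 652, and it moved no other count by over 1.5 times, while it called more genes (5119, 5587 and 4587 for the later steps, 3794 for w1118, and 228, 330 and 134 shared). With no replicate block T4 and T5 differed in 79 genes and the subtypes in 231, with fewer genes tested as well (4174 and 4049 in place of 4973 and 4856). DESeq2 called 167 genes for T4 and T5. With T4 and T5 neurons only, 1652 genes of 6357 tested differed for w1118. With types weighted equally 1956 genes changed from 72 to 96 h, and from 48 to 72 h 1032 rose and 2906 fell. A share of 75% of types, a looser rule, gave 393, 574 and 204 shared genes; sums of 20 cells left fewer types and gave 362 and 167 for the first and last step; no filter on low counts gave 154 from 48 to 72 h. All cells unthinned, with more depth, gave 1092, 1469, 1630, 1891, 1834 and 1824 genes among types from 24 to 84 h, and 1667 at 96 h, which is below the count at 60 h, while with equal cells and UMIs the ranges over draws at 60 and 96 h overlapped.

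Leaving out each sum in turn gave 3888 to 4180, 4286 to 4523 and 3082 to 3317 genes for the 3 steps of all neurons, 431 to 763 and 474 to 711 for the early steps, 2385 to 4255 for w1118 (lowest without w1118 at 96 h, highest without w1118 at 48 h set B), 220 to 267 for T4 and T5, 367 to 457 for the subtypes, and 2646 to 2760 for L1 to L5. For shared changes the sum of the same number was left out at every stage at once (6 runs), which gave 135 to 163, 196 to 236 and 71 to 95.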

Other observations

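The glycolysis list with its tests, the values at 84 h and the share of other genes that changed alike in glia were chosen after seeing the data. In glia 2139 genes changed from 24 to 48 h (1104 up, 1035 down), 2734 from 48 to 72 h (1305 up, 1429 down) and 2388 from 72 to 96 h (1020 up, 1368 down) of 7011 tested (edgeR, 6 strain sums per stage). All cells of class G were summed together. A changed makeup of glia was not tested and may contribute to these changes. From 24 to 48 h NT5E-2 (log2 fold 7.31) and the ammonium transporter gene Rh50 (5.74, from 7.86 to 471 CPM) rose, while the cell cycle phosphatase gene stg (-3.68, from 442 to 35.5 CPM) and the fatty acid binding protein gene fabp (-3.37, from 18020 to 1790 CPM) fell, and 6 of 8 cell cycle markers fell. From 48 to 72 h GlcAT-P (7.45, from 3.94 to 702 CPM) and Cyp28a5 (6.43) rose, Tsp68C (-6.21), nompA (-5.48) and alphaTub85E (-4.61) fell, 9 of 12 glial markers rose (median 2.01) and 82 of 83 ribosomal protein genes fell. From 72 to 96 h Swim (8.25), Nepl5 (7.12), the potassium channel gene Irk2 (6.72), egr (6.23) and Men-b (5.92) rose and Lip4 (-5.03), Tre1 (-4.73, from 1871 to 64.1 CPM) and Oatp74D (-4.45) fell.

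Glycolytic enzyme genes rose in both neurons and glia. In neurons 11 of 12 rose from 48 to 72 h (median log2 fold 1.90) and 11 from 72 to 96 h (1.22), after 3 rises and 3 falls from 24 to 48 h. In glia 11 of 12 (1.17) and 9 of 12 (0.78) rose. PyK rose by 3.72 in neurons and 1.24 in glia, Ald1 by 3.20 and 0.99, and Hex-A by 1.28 and 1.91 from 48 to 72 h. By the interaction the median difference of log2 changes, neurons minus glia, over the 12 enzymes was 0.847, with Hex-A (-0.71) and Ldh (-1.80, at 0.803 and 3.07 CPM in glia, adjusted p = 0.067 by edgeR) going the other way. The list was chosen after PyK and Pfk were seen among the largest rises in neurons, so this does not decide whether glycolytic genes rose more in neurons than in glia.

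A hypothesis that ecdysone response genes may change alike in neurons and glia was tested over the 3 steps: 86.5% of 37 changes past the threshold in neurons had the same direction in glia. Among the other genes 74.2% of 9933 such changes did, so that agreement was common outside the ecdysone response too. By step the shares were 92.9%, 69.2% and 100% for ecdysone response genes (of 14, 13 and 10 changes) and 78.3%, 76.5% and 66.4% for the others, with no test of the gaps. ftz-f1, for one, rose in glia by 3.89 from 48 to 72 h (39.9 to 599 CPM). The sizes of the change differed for some of the genes.

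At 84 h both Eip75B and Kr-h1 differed widely between strain sums. In neurons Eip75B was at 2020 CPM in set A line_320 and 1990 in set B line_850, and at 354, 297, 386 and 219 in the other sums, while Kr-h1 was at 79.4 CPM or more in the first pair and at 5.02 or less in the others. Glia of the same strains had Kr-h1 at 114 and 40.5 CPM, and from 0 to 8.16 in the others. On a scale from 0 at 72 h to 1 at 96 h, over 3400 genes, the first pair lay at 0.694 and 0.70 and the others at 0.599 or less. Whether the animals of the first pair were older than labelled cannot be worked out from the labels, so means and SDs at 84 h, such as 879 ± 877 CPM for Eip75B, are over sums of uncertain age. At 84 h 178 of 3416 genes were above every sum of 72 h and 96 h and 164 below. A chance of 0.0108% per gene would hold only for sums that are interchangeable across stages. Those of 72 h and 96 h were not, as 3292 genes changed between them, so this chance does not measure the support for these genes. ftz-f1 had a log2 mean of 12.44 there, against 10.95 at 72 h and 7.29 at 96 h, SIFaR 9.31, 7.74 and 4.10, and Rbp9 5.99, 8.72 and 7.68.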
